A study of Mus musculus with 3 samples.

How the data were processed

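The material was 3 CUT&Tag libraries from mouse bone marrow LSK cells, the lineage-negative, Sca-1-positive, Kit-positive fraction that holds blood stem cells and early progenitors. CUT&Tag directs a transposase through an antibody to a protein on chromatin, so that DNA close to the protein is tagged for sequencing. Per the labels' series design, the mice carried a Flag epitope tag knocked in at the N-terminus of Bcl11a, a zinc finger transcriptional repressor. The genotype label of each sample nevertheless reads wildtype. The titles number the 3 libraries as replicates of a single group, and nothing in the labels says that they came from separate animals. SDs across libraries therefore measure only the spread between these libraries, whatever its source. P-values were taken over genes, random gene lists or shifted regions within these libraries, not over animals. No untagged, antibody-free or input library was analysed here, so every enrichment is relative to the rest of the same library.

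Reads were aligned to mm10 with Bowtie2, handled with SAMtools and turned into peaks with MACS2, per the submitters' processing notes, which give no versions. Each of the 3 deposited files lists the peaks of its own library, so the libraries could be compared by overlap. For each peak the deposited files give a score, a fold enrichment (a ratio of the summit pileup to the caller's local background), −log10 p, −log10 q and the position of the summit. The deposited score was found to be 10 times the −log10 q without its decimals, and it was not used. The lowest −log10 q in the 3 lists was between 1.30 and 1.31, the q threshold of 0.05. Whether duplicate fragments were removed is not given in the sources used here.

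The deposited lists hold no fragment counts. The summit pileup and the background of each peak were solved from its fold enrichment, taken as pileup plus 1 over background plus 1, and its −log10 p, taken as a Poisson tail. Within 0.05 of a fragment, 100% of the pileups came out whole in each library. The lowest background of a library, read as its genome-wide background, was 1.07, 1.41 and 1.95 fragments per base in libraries 1, 2 and 3. By this measure the coverage of library 3 was 1.82 times that of library 1. Coverage grows with fragment length as well as fragment number, so this is not a ratio of fragment numbers. The shortest peak was 174, 199 and 221 bp in libraries 1, 2 and 3. The highest fold enrichment of each library, multiplied by its shortest peak and divided by 10000, was 0.902, 0.907 and 0.930. Fold enrichment therefore reached a ceiling set by the 10 kb local background, and pileup over the library background was used beside it.

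Peaks of the 3 libraries on the autosomes, X and Y were joined wherever they overlapped by at least 1 bp. A region with a peak of all 3 libraries is called reproducible, and its value in a library is that of the library's strongest peak in it. Pairwise overlap was compared with 1000 circular shifts of one list along each chromosome (one-sided). The caller's fold enrichment is the authors' own value for each peak and was used to describe and rank peaks.

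Genes were taken from a RefSeq gene table of GRCm38.p6, the assembly behind mm10. That table gives the outer ends of each gene without strand, transcripts or exons, and no genome sequence was used here. The planned promoter (within 1 kb of a transcription start) was therefore replaced by either end: a gene counted as occupied when a reproducible region came within 1 kb of an annotated outer end. Exon and UTR classes, the planned motif search and the planned adjustment for CpG and GC content were not run. Distal regions have their summit over 1 kb from both ends of every gene, and each was assigned to the nearest end of a protein-coding gene within 100 kb. Internal start sites count as distal under this rule. A region whose edge came within 1 kb of an end while its summit lay farther off counted in both ways, and a region between close genes counted for each of them.

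For gene lists, 3 tests were run on 21 of them, each with Benjamini-Hochberg adjustment over the lists tested. Occupancy was compared with all other protein-coding genes by Fisher's exact test (two-sided). Strength was the list's median of mean log2 fold enrichment over the libraries, among occupied members, against 100000 random lists of occupied genes drawn with replacement (two-sided permutation test), for the 16 lists with at least 5 occupied members. Distal regions per gene were compared with 10000 random lists matched on the length of the gene's nearest-end domain in 10 bins (two-sided permutation test). Single-library ratios rest on 2000 random lists. Some genes stand in several lists, genes in clusters share regions, and neither was corrected for. The tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where said otherwise. That rule takes Bcl11a, the 10 strongest gene ends, the 10 strongest distal regions, and the 5 genes with most distal regions. From each list it takes up to 4 of the strongest occupied members and, alphabetically, up to 4 with no peak of any library at either end. Strongest means the highest value of the lowest of the 3 libraries' fold enrichments. Gene names added outside the rule are those with many distal regions, and they were chosen after their values were seen. Some genes that the rule names are not reported here.

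The steps were tested on simulated data. Of 20000 simulated peaks, 100% of pileups were recovered exactly, and 9.71% came out whole by chance when the p-values were altered. The overlap test called 1 of 20 unrelated pairs of lists and 20 of 20 with 30% shared peaks. In 100 simulations over 21887 genes, 0.20% of unchanged lists were called for occupancy, 0.35% for strength and 0% for distal regions. A 28-member list raised to 75% occupied was called in 69 of 100 simulations, one with 2-fold strength in 100, and one with 3-fold distal regions in 74. A list that was not called may therefore still differ. Alternatives covered a stricter q, fewer peaks, stricter overlap, fewer libraries, other windows and reaches, other measures of strength and other backgrounds. They used 200 shifts (100 for reciprocal overlap), and those of the strength test, apart from pileup, used 20000 random lists. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.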

Results

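CUT&Tag signal for Flag-tagged Bcl11a was mapped in sorted bone marrow LSK cells, the compartment of mouse blood stem and early progenitor cells. No untagged library was analysed here. Regions at gene ends and elsewhere, called occupied below, were therefore not told apart from open chromatin tagged without the protein. The design text gives the purpose as finding how Bcl11a acts in blood formation. It implies the questions of where in the genome the tagged protein lies and which genes those places belong to. Single lists of peaks described 3 libraries of the same group, with no second group to compare. Library 1 held 38739 peaks over 16.5 Mb, library 2 held 36466 over 19.5 Mb and library 3 held 43469 over 23.6 Mb. Their median widths were 347, 450 and 452 bp. The median fold enrichment was 5.16, 5.25 and 4.69, and the median summit pileup was 14, 18 and 20 fragments. The background that the lists imply was 1.07, 1.41 and 1.95 fragments per base, so a peak in library 1 rests on fewer fragments than one of equal enrichment in library 3.

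The 3 libraries placed most of their peaks at the same sites. Joined together they made 60816 regions, of which 22987 (37.8%) held a peak of every library, 9831 a peak of 2 libraries and 27998 a peak of 1 library. These 22987 reproducible regions covered 18.7 Mb, with a median width of 752 bp. They took 62.4% of the peaks of library 1, 64.1% of library 2 and 53.8% of library 3. Between pairs of libraries, 61% to 75.8% of one list's peaks were overlapped by the other, against means of 1.48% to 1.99% for shifted lists (permutation p = 0.000999 for each of 6 comparisons, the smallest that 1000 shifts can give). Reproducible peaks were the stronger ones in every library, with a median fold enrichment of 6.19 against 4.14 for peaks of library 1 alone, 6.32 against 4.02 in library 2 and 5.97 against 3.73 in library 3. Across reproducible regions, which are not independent replicates, Spearman's rho of fold enrichment between libraries was 0.76 to 0.80 and Pearson's r of its log2 was 0.80 to 0.83.

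Reproducible regions gathered at gene ends. Of the 22987 regions, 8515 (37.0%) had their summit within 1 kb of an end of a protein-coding gene, against a mean of 3.23% for shifted regions, an 11.5-fold excess. Ends of other genes held 6.18% against 3.27%. Fewer regions than in shifted sets lay inside protein-coding genes (33.6% against 38.1%), inside other genes (4.36% against 6.91%) and outside any gene (18.8% against 48.5%). Each of these 5 differences had p = 0.001998 in the two-sided permutation test, the smallest that 1000 shifts can give. An end of 9902 of 21887 protein-coding genes (45.2%) was occupied. Among genes longer than 5 kb, 7996 had 1 end occupied and 560 had both, so that 93.5% of the occupied ones had a region at a single end. The annotation used carries no strand, so the occupied end was not assigned to the start or the finish of transcription. Taken singly, the libraries occupied 10936, 11485 and 11803 genes.

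The Bcl11a gene itself lay among 11 reproducible regions. The gene (chromosome 11, 24076564 to 24173558, mm10) had regions at its lower-coordinate end, inside it and beyond both ends. The strongest lay outside the gene, 26860 bp beyond the higher-coordinate end (24199797 to 24201065), with a fold enrichment of 12.8 ± 1.77 (SD, n = 3). The regions at 24242869 to 24243540 and 24184886 to 24185763, on the same side, had 9.75 ± 0.89 and 9.50 ± 0.97 (SD, n = 3). Near the lower-coordinate end, a region inside the gene (24077053 to 24078082) had 8.08 ± 0.98 (SD, n = 3) and summit pileups of 94, 155 and 142 fragments in libraries 1, 2 and 3, where the strongest region had 100, 106 and 127. The region over the annotated end itself (24075951 to 24076707) had a fold enrichment of 3.09 ± 0.35 (SD, n = 3), with pileups of 35, 44 and 63 fragments. Of the 11 regions, 10 counted as distal, against 1.05 expected for a gene with as long a domain. The tag was knocked in at this locus, and no test was run on the single gene.

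**Figure D1:**
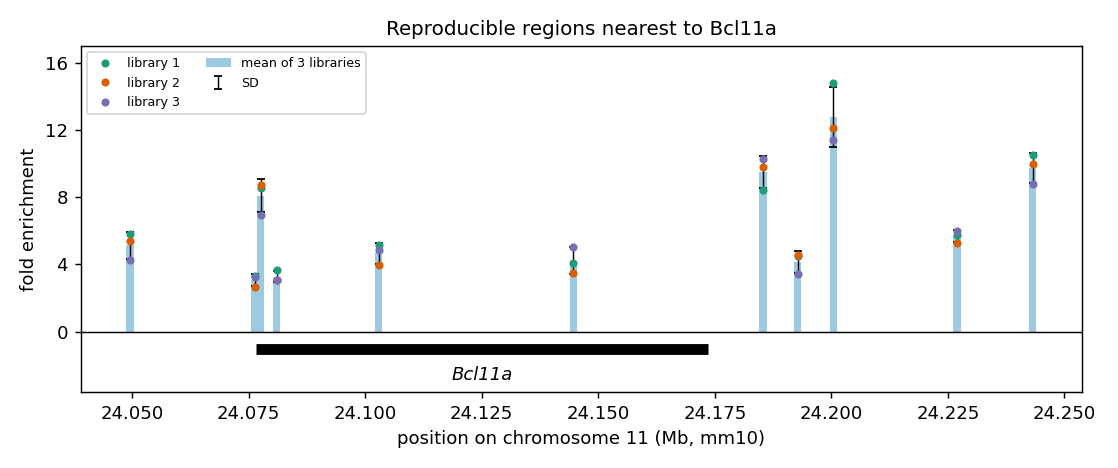
Fold enrichment (y axis) of the 11 reproducible regions nearest to Bcl11a along chromosome 11 (x axis, Mb of mm10), with bars for the mean of 3 libraries, error bars for the SD, points for each library and the gene as a black line. The highest bar, 12.8 ± 1.77, stands outside the gene beyond its higher-coordinate end.

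Ends of genes that run stem cells and the cell cycle were occupied more often than those of other protein-coding genes. Among stem cell transcription factors, 21 of 28 members were occupied (75% against 45.2% of other genes, adjusted p = 0.0033, Fisher's exact test over 21 lists). This call was lost with the 10000 strongest peaks of each library (39.3%, adjusted p = 0.060), with 50% reciprocal overlap (46.4%, 0.23) and with a 250 bp window (60.7%, 0.052), all by the exact test. Occupied members included Erg, Etv6 and Lyl1, which are needed for blood stem cells, and Mecom, a regulator of stem cell quiescence. Mecom had a fold enrichment of 9.59 ± 0.22, Erg 9.71 ± 1.17, Etv6 9.03 ± 0.85 and Lyl1 8.95 ± 1.06 (SD, n = 3). No library had a peak at either end of Fli1, Hoxb5, Ldb1 or Lmo2. A gene without a peak at its ends can still have distal regions nearest to it. A peak at a start site inside the gene can be among these, so an unoccupied end does not show an unoccupied promoter. Fli1 had 7 distal regions, Ldb1 and Lmo2 3 each, and Hoxb5 0. Genes of quiescence and cell cycle entry were occupied in 27 of 31 cases (87.1%, adjusted p = 6.2e-06, Fisher's exact test). Cdkn2c, an inhibitor of the G1 kinases, stood at 15.1 ± 1.02 and its target kinase gene Cdk4 at 11.6 ± 1.73. Mxd1, an antagonist of Myc, had 13.1 ± 0.16 and the tumour suppressor Rb1 9.80 ± 0.74 (SD, n = 3). Cdkn1a and Ndn had no peak of any library at either end, though Cdkn1a had 3 distal regions (0.41 expected) and Ndn 0.

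Corepressor subunits, among them partners of Bcl11a, were occupied in 27 of 29 cases (93.1%, adjusted p = 3.7e-07, Fisher's exact test). The list was led by Gatad2a of the NuRD complex at 14.3 ± 1.95, the histone deacetylase gene Hdac2 at 11.5 ± 0.40 and the SWI/SNF genes Actl6a and Smarcc1 at 12.5 ± 0.58 and 11.5 ± 0.56 (SD, n = 3). Interferon and inflammatory genes were occupied in 24 of 32 cases (75%, adjusted p = 0.0021, Fisher's exact test), among them the receptor genes Ifnar1 and Ifngr1 at 13.7 ± 1.19 and 13.5 ± 1.51. The induced genes Cxcl10, Ifit1, Il1b and Isg15 had no peak of any library at either end. Genes of p53, DNA damage and apoptosis were occupied in 22 of 32 cases (68.8%, adjusted p = 0.017, Fisher's exact test), a call lost in the exact test with the 10000 strongest peaks (34.4%, 0.12) and with 50% reciprocal overlap (50%, 0.094). Atm, the DNA damage kinase, had 13 ± 1.40 and Apaf1, the caspase activator, 11.3 ± 0.53 (SD, n = 3).

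Genes that every cell uses were occupied as widely. The shares were 67 of 81 ribosomal protein genes (82.7%), 30 of 39 proteasome genes (76.9%) and 36 of 49 genes of mitochondrial complex I (73.5%), with adjusted p of 2.2e-11, 0.00020 and 0.00020 (Fisher's exact test). Rpl27 had a fold enrichment of 16.2 ± 1.04, Psmd1 17.5 ± 1.92 and Ndufa4 17.5 ± 2.0 (SD, n = 3). With the 10000 strongest peaks the proteasome call was lost (28.2%, adjusted p = 0.31, exact test). Histone genes were occupied in 60 of 67 cases (89.6%, adjusted p = 2.3e-13, Fisher's exact test), although their clusters shared 36 regions. Set against ribosomal protein, proteasome and complex I genes alone, a comparison chosen after seeing the data, 0 of 18 lists were occupied more often at adjusted or unadjusted p under 0.05 in Fisher's exact test. Of the same 18 lists, 10 were occupied less often.

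For lists of blood lineage genes, which hold regulators as well as markers, the share of occupied genes did not pass the threshold in either direction. The counts were 10 of 30 lymphoid genes (33.3%), 14 of 30 myeloid genes (46.7%) and 13 of 33 erythroid and megakaryocyte genes (39.4%), with adjusted p of 0.25, 1.0 and 0.63 in Fisher's exact test. The strongest occupied lymphoid genes included Tcf3 at 12.7 ± 2.06, Satb1 at 7.12 ± 1.17 and Notch1 at 6.85 ± 0.53 (SD, n = 3). The T cell transcription factor gene Bcl11b, the chemokine receptor gene Ccr9 and Cd3g, which encodes a component of the T cell receptor complex, had no peak at either end. Among myeloid genes, Spi1, which encodes PU.1, had 6.30 ± 0.56 and Mpo 6.94 ± 1.20 (SD, n = 3). The granule genes Elane, Ctsg and Camp had no peak at either end. Among erythroid and megakaryocyte genes, Hemgn had 12.8 ± 1.17, Nfe2 12.6 ± 1.58 and Itga2b 11.2 ± 0.08 (SD, n = 3). Gata1, Alas2 and Car1 had no peak at either end. Gata1 and Alas2 lie on chromosome X, where 18.5% of protein-coding genes were occupied, against 47.0% on autosomes. Genes reported as higher in aged stem cells (13 of 34, 38.2%, adjusted p = 0.54), stem cell surface and signalling genes (15 of 26, 57.7%, 0.28), MHC genes (13 of 19, 68.4%, 0.087) and genes tied to Bcl11a in earlier work (15 of 25, 60%, 0.21) were not called by the exact test either. Aged stem cell genes were called below other genes with −log10 q of at least 5 (11.8%, adjusted p = 0.0027) and with the 10000 strongest peaks (0 of 34 members, 0.0027) in the exact test. MHC genes were called above without library 1 (78.9%, adjusted p = 0.017), in at least 2 libraries (78.9%, 0.030) and with a 3 kb window (84.2%, 0.0067), as was the list tied to Bcl11a with a 3 kb window (76%, 0.021), by the exact test. In the list tied to Bcl11a, Carm1 had 13.4 ± 1.58 and Flt3, a receptor of multipotent progenitors, 11.7 ± 1.47 (SD, n = 3). The embryonic globin genes Hbb-y and Hbb-bh1 had no peak at either end.

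Genes of other tissues were occupied less often than other protein-coding genes. An end was occupied in 4 of 1110 olfactory receptor genes (0.36%, adjusted p = 1.2e-289), 1 of 109 keratin genes (0.92%, 2.5e-26), 4 of 27 neuronal genes (14.8%, 0.0028) and 2 of 22 hepatocyte genes (9.09%, 0.00091), all by Fisher's exact test. Bone marrow stroma and endothelial genes, whose expression in LSK cells was not measured here, were occupied in 4 of 23 cases (17.4%, adjusted p = 0.016, Fisher's exact test). The occupied ones were Sp7 at 6.8 ± 0.13, Kdr at 6.76 ± 0.98, Sox17 at 6.15 ± 0.52 and Pdgfrb at 4.85 ± 1.75 (SD, n = 3). Without library 3 the hepatocyte list had 22.7% occupied (adjusted p = 0.049, exact test) and without library 1 13.6% (0.0019), and in library 1 alone it had 31.8%. Keratin genes had 1.83% without library 1 or library 3, and olfactory receptor genes 0.54% without library 3. In libraries 1, 2 and 3 taken singly the stroma list had 21.7%, 34.8% and 52.2% occupied, where all protein-coding genes had 50%, 52.5% and 53.9%. Without library 1 the stroma list had 30.4% occupied and lost its call (adjusted p = 0.13, exact test). With the 10000 strongest peaks of each library the calls for hepatocyte genes (9.09%, adjusted p = 0.34) and stroma genes (4.35%, 0.12) were lost in the exact test, and the stroma call was also lost with a stricter q (17.4%, 0.072), in at least 2 libraries (34.8%, 0.18) and with a 3 kb window (30.4%, 0.079).

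**Figure D2:**
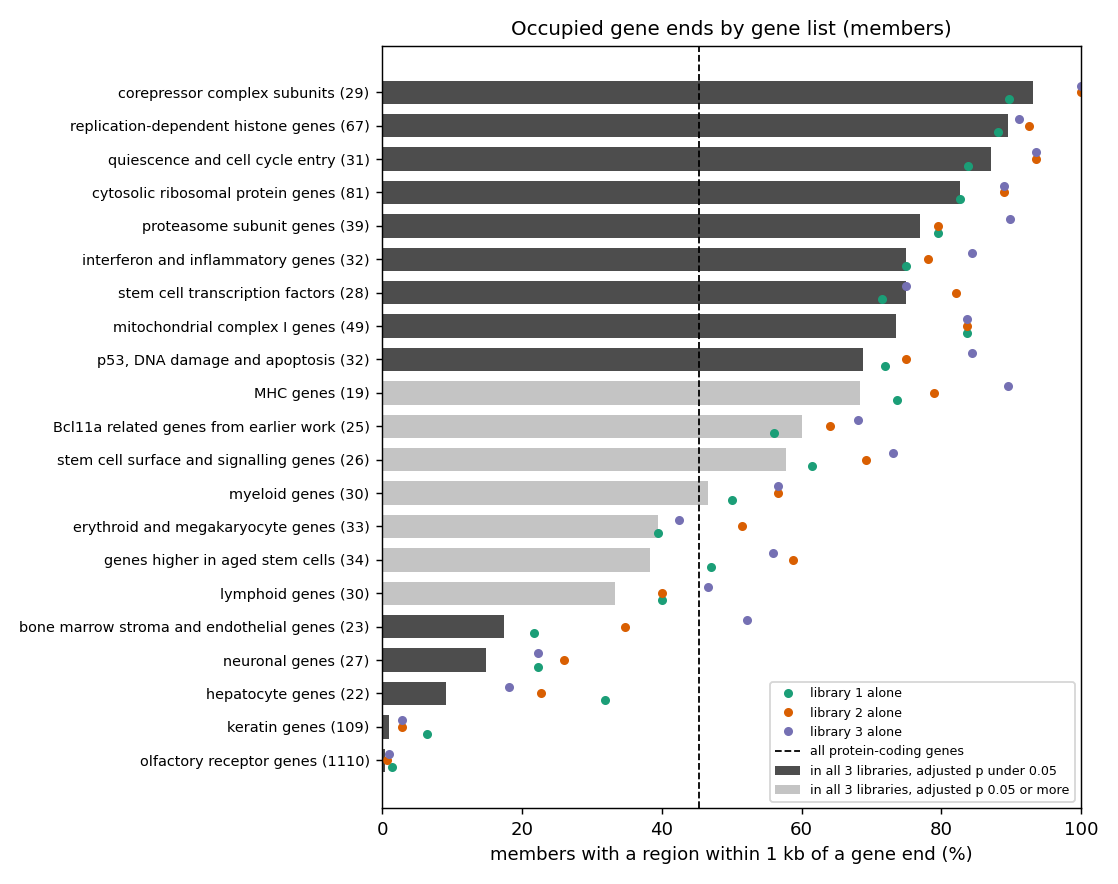
Percentage of the members of 21 gene lists (x axis) with a region within 1 kb of a gene end, with bars for regions of all 3 libraries (dark where Fisher's exact test gave an adjusted p under 0.05), coloured points for each library alone and a dashed line for all protein-coding genes (45.2%). Corepressor genes stand highest at 93.1% and olfactory receptor genes lowest at 0.36%.

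Where gene ends were occupied, genes reported as higher in aged stem cells carried weaker signal than other occupied genes. The median of log2 fold enrichment of the 13 occupied members lay below that of all occupied genes by a difference of -0.59 (adjusted p = 0.0093, permutation test over 16 lists). Their strongest members were Fhl1 at 8.72 ± 1.09 and Jam2, a junctional adhesion molecule gene, at 6.50 ± 1.41 (SD, n = 3). With summit pileup over the library background as the measure, a choice made after seeing the data, the difference was -0.99 (adjusted p = 0.0016, permutation test). Myeloid genes had a difference of -0.53 (adjusted p = 0.011) and histone genes one of -0.25 (0.023) in the permutation test. Neither call stood in the permutation test with pileup as the measure: myeloid genes came to -0.15 (adjusted p = 0.73) and histone genes turned to 0.68 above (0.00096). Quiescence genes went from -0.09 (adjusted p = 0.69) to 0.83 (0.0036) in the permutation test. In the permutation test the histone call was also lost without library 1 (-0.19, adjusted p = 0.20) and without library 2 (-0.19, 0.30), and the myeloid call without library 1 (-0.41, 0.14). Neither was called in the permutation test with regions in at least 2 libraries (myeloid -0.45, adjusted p = 0.070, and histone -0.16, 0.38) or with −log10 q as the measure (-0.91, 0.12, and 0.35, 0.30). Erythroid and megakaryocyte genes, at 0.19 (adjusted p = 0.65), were called above in the permutation test with −log10 q of at least 5 (0.50, 0.035), 50% reciprocal overlap (0.50, 0.034) and a 250 bp window (0.59, 0.019). By fold enrichment, 0 of 16 lists were stronger than other occupied genes at adjusted or unadjusted p under 0.05 in the permutation test.

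Away from gene ends, regions gathered around regulators of blood cells. Of the reproducible regions, 13051 (56.8%) were distal and 11876 of them had a protein-coding gene end within 100 kb, an average of 0.543 per gene. The 28 stem cell transcription factors had 88 distal regions, 4.42 times the mean of random lists matched on domain length (adjusted p = 0.00070, the smallest the permutation test gave). In single libraries the ratio was 3.91 ± 0.23 (mean ± SD, n = 3). Runx1, the master regulator of blood stem cell emergence, and Cbfa2t3, a corepressor gene, had 10 distal regions each. Erg and Etv6 had 8 each, Fli1 7, Meis1 6 and Lyl1 5, and Fli1 had these without a peak at either of its ends.

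Blood lineage lists that were not called at gene ends did stand out here. Myeloid genes had 50 distal regions over 30 genes, 3.55 times the random mean, and lymphoid genes 55 over 30 genes, 3.25 times (adjusted p = 0.00070 for each, permutation test). In single libraries these ratios were 2.73 ± 0.20 and 2.77 ± 0.26 (mean ± SD, n = 3). Cebpb had 10 distal regions and Irf8 7, both myeloid transcription factors. Lef1 had 9, Id2 8 and Foxo1 7 among lymphoid regulators. In each of these lists 17 of the 30 genes had a distal region. Among members that are not transcription factors, Itgam had 4 and Fcgr3 and Dntt 3 each, while Camp, Cd68, Ctsg, Elane and Cd3g had 0. Erythroid and megakaryocyte genes had a ratio of 2.51 (adjusted p = 0.015, permutation test), with 9 regions near Zfpm1, the partner gene of GATA1. Genes tied to Bcl11a in earlier work had 3.21 (0.00070), genes of quiescence and cell cycle entry 3.10 (0.00070), interferon and inflammatory genes 2.54 (0.0094) and stem cell surface and signalling genes 2.35 (0.018). Bcl11a is itself a member of the list tied to it and gave 10 of that list's 51 distal regions. Without it, a test chosen after seeing the data, the ratio was 2.76 over 24 genes (adjusted p = 0.0063, permutation test). Cdk6 had 6 distal regions, Irf2 9, Cd9 7 and Kit 4. With the 10000 strongest peaks of each library the permutation test no longer called the stem cell surface (2.20, adjusted p = 0.22), erythroid and megakaryocyte (2.68, 0.15) and interferon (2.66, 0.13) lists.

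For 11 of the 21 lists the number of distal regions did not pass the threshold in either direction, which does not show that it equalled that of matched genes. The ratios were 1.99 for corepressors (unadjusted p = 0.029, adjusted p = 0.056), 2.18 for MHC genes (0.13), 1.61 for p53 and DNA damage genes (0.22) and 1.35 for stroma and endothelial genes (0.51) in the permutation test. Genes reported as higher in aged stem cells had 1.0 (0.98), ribosomal protein genes 1.34 (0.36), proteasome genes 0.83 (0.82), neuronal genes 0.68 (0.51), hepatocyte genes 0.70 (0.71), histone genes 0.45 (0.22) and complex I genes 0.40 (0.10). Olfactory receptor genes had 0.043 times the random mean (adjusted p = 0.00070) and keratin genes 0.33 (0.0024) in the permutation test. Without library 3 the hepatocyte ratio was 1.32 (adjusted p = 0.54, permutation test). Keratin genes lost their call with the 10000 strongest peaks (0.28, adjusted p = 0.15, permutation test), and complex I genes were called below with a 50 kb reach (0.32, 0.046). With −log10 q of at least 5 the permutation test called corepressors (2.41, adjusted p = 0.020) and p53 genes (2.23, 0.034). Corepressors were also called with the 10000 strongest peaks (3.09, 0.047) and 50% reciprocal overlap (2.45, 0.017). The permutation test called the corepressor list without library 1 (1.99, adjusted p = 0.039) or library 3 (2.01, 0.037), and the MHC list without library 3 (2.63, 0.037). When random lists were also matched on an occupied end, chosen after seeing the data, the interferon list (1.87, adjusted p = 0.066) and the keratin list (0.49, 0.10) lost their calls and complex I genes were called below (0.34, 0.036) in the permutation test.

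**Figure D3:**
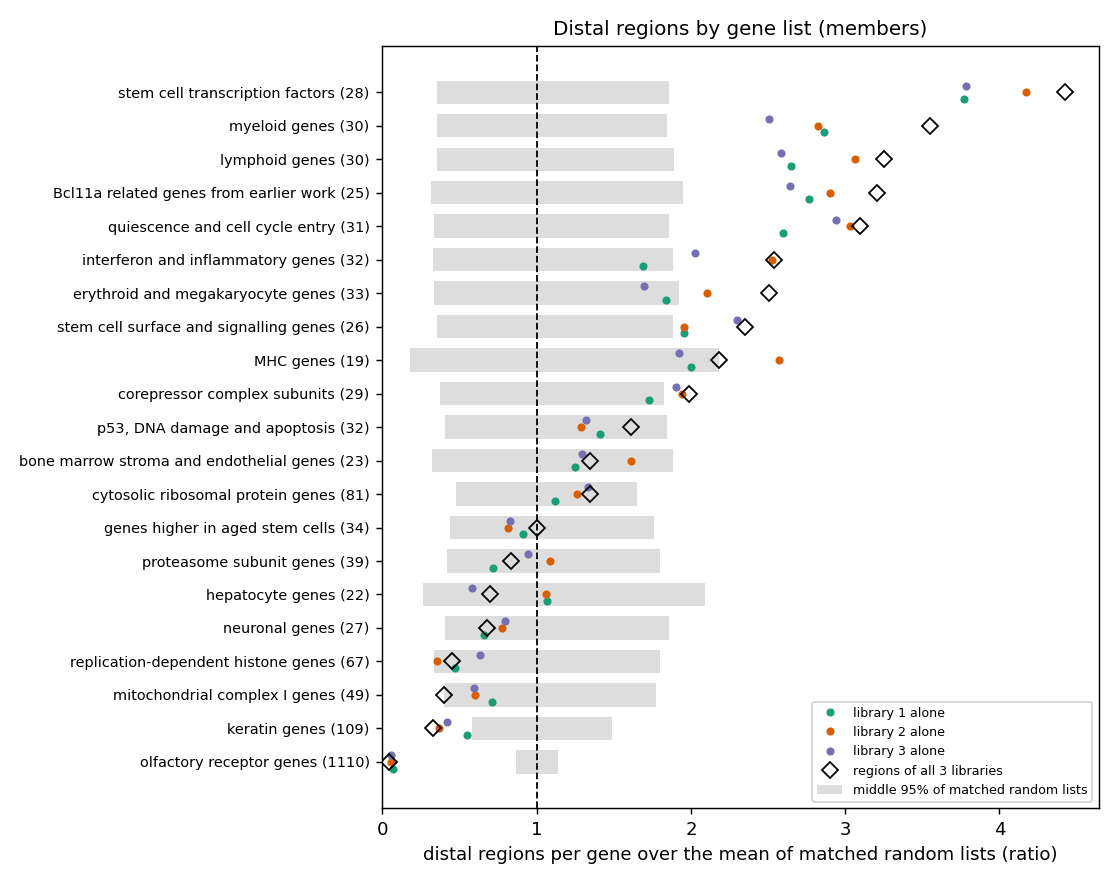
Distal regions per gene in 21 gene lists, divided by the mean of random lists matched on domain length (x axis, ratio), with diamonds for regions of all 3 libraries, coloured points for each library alone and grey bars for the middle 95% of random lists. Stem cell transcription factors stand farthest right at 4.42 and olfactory receptor genes farthest left at 0.043.

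The gene ends and distal regions of highest fold enrichment lay near genes outside the blood lists, and the distal ones stood close to the ceiling of the measure. Among gene ends, the 10 strongest belonged to Wls, Lars2, Slc22a29, Sspn, Gm32584, Nt5dc3, Zfp963, Pspc1, Tmem260 and Anapc5. They ran from 42.9 ± 4.42 at Wls (chromosome 3, 159939405 to 159939729) and 38.6 ± 2.10 at Lars2 (chromosome 9, 123461792 to 123462280) to 18.0 ± 0.57 at Anapc5 (SD, n = 3). The region at Wls was also the last reproducible region of chromosome 3. The 10 strongest distal regions had the nearest protein-coding genes Chl1, Gm40892, Gtpbp4, Rab10, Creb3l1, Lama1, Atrnl1, Flt1, Adgre5 and Asmt. Their fold enrichments, 42.9 to 46.3, stood against highest values of 51.8, 45.6 and 42.1 in libraries 1, 2 and 3. Their pileups were 506 to 1266 times the library background, and for Gm40892 and Rab10 the gene end was over 100 kb away. No list of known artefact regions was applied, so whether these are binding sites was not tested, and the gene names give only their positions.

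Chromosome X carried few regions. It had 1.74 reproducible regions per Mb, where autosomes had 5.90 to 16.6. An end of 179 of 966 X-linked protein-coding genes was occupied (18.5%), against 9721 of 20665 autosomal genes (47.0%; odds ratio 0.256, Fisher's exact test across genes, p = 1.1e-73), and the lowest autosome had 38.7%. Chromosome Y had 25 reproducible regions, 10 of them before the last 500 kb of the chromosome's span. The sex of the animals is not given in the sources used here, and it was not inferred from these regions. On 14 of 21 chromosomes the last reproducible region lay beyond the last annotated gene with a pileup of at least 100 times the library background. These terminal regions, 304 to 799 bp wide, reached 299 to 4790 times the background, where the median reproducible region had 17.7 times. In all, 433 reproducible regions reached 100 times.

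**Figure D4:**
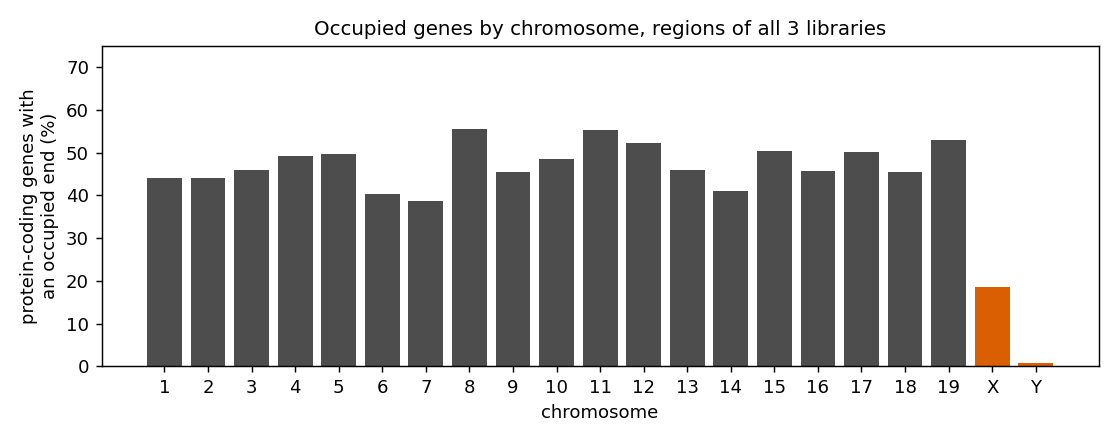
Percentage of protein-coding genes with a reproducible region at an end (y axis) on each chromosome (x axis), with autosomes in grey and X and Y in orange. Autosomes stand between 38.7% and 55.6%, and X at 18.5%.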

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

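Peaks on the mitochondrial chromosome stood outside every comparison, which used the autosomes, X and Y, and were noted because the lists hold signal there. Library 1 had 8 such peaks and libraries 2 and 3 had 7 each. Their highest summit pileups were 2094 fragments in library 1, 3091 in library 2 and 3921 in library 3. In each library the highest lay in the last mitochondrial peak, which ended at base 16284 and had a fold enrichment of 4.81, 4.37 and 4.95. No control library was analysed here, and no explanation was tested.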

How the results depend on the processing

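Of 703 pairs of a result and an alternative, 576 kept their direction and their side of the threshold or, for values without a test, stayed within 1.5 times or 1 SD. The direction turned in 56, most of them lists that passed the threshold in neither setting. The excess at protein-coding gene ends held under 9 of 9 alternatives, with 26.4% to 49.9% of regions. Pairwise overlap stayed above the shifted lists in each alternative, at 46.7% to 83.8%. Leaving out each library gave 25124 to 27270 reproducible regions and 10105 to 10674 occupied genes. The stem cell transcription factor, myeloid and lymphoid lists kept their excess of distal regions under each alternative run. Unless stated, the cause of a change was not tested. Values in brackets are adjusted p. The comparisons with housekeeping genes, with pileup as strength, with matching on an occupied end, without Bcl11a in its own list, and without regions of at least 100 times the background were chosen after seeing the data, the last changing no call. No paired analysis was possible because the libraries form a single group. The motif search and the adjustment for GC and CpG content were not run, as no genome sequence was used here. A list with fewer than 5 occupied members under a setting has no strength value there. Depth limits weak peaks: the lowest summit pileups were 6, 7 and 8 fragments in libraries 1, 2 and 3.

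With −log10 q of at least 5, peaks numbered 22862, 24179 and 28461, and reproducible minus single-library fold enrichment was 1.93 (2.20 in the main setting). Occupancy of aged stem cell genes fell below chance at 11.8% (0.0027), and the stroma list lost its call at 17.4% (0.072). Strength gained 1 list above, erythroid and megakaryocyte at 0.50 (0.035), and the list tied to Bcl11a at -0.39 (0.031). Distal ratios gained corepressors at 2.41 (0.020) and p53 genes at 2.23 (0.034). With the 10000 strongest peaks, 7210 regions and 4515 occupied genes were left. Occupancy calls were lost for stem cell transcription factors at 39.3% (0.060), p53 genes at 34.4% (0.12), proteasome genes at 28.2% (0.31), hepatocyte genes at 9.09% (0.34) and stroma at 4.35% (0.12), while aged stem cell genes were at 0.0% (0.0027). Strength gained calls for quiescence at -0.27 (0.037) and MHC genes at -0.44 (0.037). Distal calls were lost for stem cell surface genes at 2.20 (0.22), erythroid and megakaryocyte at 2.68 (0.15), interferon at 2.66 (0.13) and keratin at 0.28 (0.15), leaving 1 list below, and corepressors were gained at 3.09 (0.047). Fewer regions were tested here.

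With regions in at least 2 of 3 libraries, reproducible minus single-library fold enrichment was 1.66. MHC occupancy was called at 78.9% (0.030), stroma lost its call at 34.8% (0.18), and strength kept 1 list below, without myeloid at -0.45 (0.070) and histone genes at -0.16 (0.38). With 50% reciprocal overlap, occupancy calls were lost for stem cell transcription factors at 46.4% (0.23) and p53 genes at 50% (0.094). Strength gained 1 list above, erythroid and megakaryocyte at 0.50 (0.034), and corepressors gained a distal call at 2.45 (0.017). Leaving out each library gave MHC occupancy of 68.4% to 78.9%, stroma occupancy of 17.4% to 30.4%, myeloid strength of -0.56 to -0.41, histone strength of -0.30 to -0.19, corepressor distal ratios of 1.65 to 2.01 and MHC distal ratios of 2.09 to 2.63, each crossing the threshold at least once. Hepatocyte occupancy ran from 9.09% to 22.7% on its side of the threshold.

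With a 250 bp window, stem cell transcription factors were at 60.7% (0.052), and strength gained 1 list above, erythroid and megakaryocyte at 0.59 (0.019). With a 3 kb window, occupancy gained the list tied to Bcl11a at 76.0% (0.021) and MHC genes at 84.2% (0.0067), stroma lost its call at 30.4% (0.079) and histone strength its own at -0.22 (0.063). With a 50 kb reach, complex I distal regions were called below at 0.32 (0.046). With −log10 q as the strength, the mean correlation between libraries was 0.814 (0.785 in the main setting), and 1 list stayed below: myeloid genes were at -0.91 (0.12) and histone genes turned to 0.35 (0.30). With pileup over background as the strength, 2 lists were above and 1 below: quiescence turned to 0.83 (0.0036), histone genes to 0.68 (0.00096), and myeloid genes were at -0.15 (0.73). With matching on an occupied end too, interferon was at 1.87 (0.066), keratin at 0.49 (0.10) and complex I below at 0.34 (0.036).

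Against housekeeping genes, 78.7% of them occupied, 0 lists were above and 10 below. The direction turned for stem cell transcription factors at 75% (0.64), interferon at 75% (0.64), p53 genes at 68.8% (0.32), stem cell surface genes at 57.7% (0.048) and myeloid genes at 46.7% (0.0011). The calls above were lost for quiescence at 87.1% (0.41), corepressors at 93.1% (0.11) and histone genes at 89.6% (0.092). Lymphoid genes at 33.3% (5.5e-06), erythroid and megakaryocyte at 39.4% (4.7e-05) and aged stem cell genes at 38.2% (2.6e-05) were called below. The higher occupied share of this background accounts for these turns by construction.

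The direction of lists that passed the threshold in neither setting turned as follows, with adjusted p from 0.077 to 1.0. In occupancy, myeloid genes turned at 30% with the stricter q, 10% with the 10000 strongest peaks, 33.3% with the 250 bp window and 50% in at least 2 libraries. Without each library they ran from 43.3% to 50%, turning without library 1 and library 2 and not without library 3. With the 10000 strongest peaks, stem cell surface genes turned at 19.2% and erythroid and megakaryocyte genes at 24.2%. Lymphoid genes turned at 53.3% with the 3 kb window, aged stem cell genes at 52.9% in at least 2 libraries, and the list tied to Bcl11a at 60% and MHC genes at 68.4% against housekeeping genes. In distal regions, aged stem cell genes turned at 0.97 with the stricter q, 0.91 in at least 2 libraries and 0.958 to 0.994 without each library. Proteasome genes turned at 1.09 with the 10000 strongest peaks and ran from 0.745 to 1.07 without each library, and hepatocyte genes ran from 0.626 to 1.32. In strength, the stricter q turned interferon to -0.0074 and proteasome genes to -0.046. The 10000 strongest peaks turned stem cell surface genes to 0.23, the list tied to Bcl11a to 0.041, corepressors to 0.0029, p53 genes to -0.041, interferon to -0.13 and proteasome genes to -0.011. Reciprocal overlap turned stem cell transcription factors to 0.011, interferon to -0.026 and proteasome genes to -0.045. The 250 bp window turned corepressors to 0.047, regions in at least 2 libraries turned ribosomal protein genes to 0.0088, and proteasome genes ran from -0.015 to 0.078 without each library. With −log10 q, stem cell transcription factors turned to 0.13, quiescence to 0.62, the list tied to Bcl11a to 0.0040, corepressors to 0.35, p53 genes to -0.031, MHC genes to 0.25 and proteasome genes to -0.26. With pileup, stem cell transcription factors turned to 0.27, the list tied to Bcl11a to 0.27, corepressors to 0.42, p53 genes to -0.11, MHC genes to 0.25, ribosomal protein genes to 0.011 and proteasome genes to -0.40.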

Other observations

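The tests of chromosome ends, the matching on an occupied end and the comparison of blood with housekeeping genes were chosen only after the patterns had been seen. Among the genes with the most distal regions over the genome, taken by the rule for named genes, were Runx3 with 17, Septin9 and Zmiz1 with 15 each, and Prex1 with 14. Runx3 is a relative of Runx1 with roles in lymphocytes, and Zmiz1 encodes a coactivator that works with Notch1. Each of these also had a reproducible region at an end, from 4.93 ± 0.76 at Septin9 to 9.08 ± 1.21 at Runx3 (fold enrichment, SD, n = 3). Counts varied within lists, as genes chosen after their values were seen show: Krt80 had 5 distal regions in the list that was lowest but for olfactory receptors, and Rplp1 had 6 among ribosomal protein genes.

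Distal regions gathered near blood regulators. A general tie between an occupied end and distal regions was not the whole cause: with random lists matched on an occupied end too, stem cell transcription factors still had 3.21 times the random mean, above the upper end of the middle 95% of random lists at 1.72. Library-specific regions had no part in the main ratio of 4.42, which used only regions of all 3 libraries. Weak regions do not account for it either. Over each library alone and the 10000 strongest peaks of each library, the lowest ratio was 3.77, that of library 1 alone. The ratio with the 10000 strongest peaks was therefore no lower than this. Lists of a single library add weak and library-specific regions to the shared ones, so they could not decide this. Ribosomal protein, proteasome and complex I genes did not share it. The 146 blood genes had a mean of 1.24 distal regions beyond expectation and these 169 housekeeping genes -0.03 (p = 5.0e-05, the smallest the permutation test can give). These lists had already been seen to differ, so the p-value only restates that. Genes of quiescence (ratio 3.10) and interferon genes (2.54) were called above too, while corepressors (1.99) and p53 genes (1.61) were not. An excess near active genes of other kinds therefore stays open. Open chromatin tagged without the protein stays open as a possible explanation, as does binding of Bcl11a, because no untagged library was analysed here.

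Chromosome X had few occupied genes. A single X copy would lower the pileup. Halving the pileup and background of autosomal peaks left 39.9% of autosomal genes occupied, where X had 18.5%. The genome-wide background of a library would not fall with a single X copy, however. A single copy could therefore cost more genes than this halving did, and the test cannot decide whether copy number is the cause. A shortage of genes in constant use on X falls short as the whole cause. Of 7 ribosomal protein, proteasome and complex I genes on X, 3 were occupied (42.9%), against 80.2% on autosomes (Fisher's exact test, p = 0.038). This test rests on 7 genes. Repeated gene families on X and the sex of the animals were not tested, and no biological explanation was tested.

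Very high pileups stood at chromosome ends. If they were collapsed repeat copies read at a single rate per library, their pileup in library 3 over library 1 would match that of other regions of at least 100 times the background, but its median was 1.02 in 14 terminal regions and 1.49 in 419 others (p = 5.0e-05, the smallest the permutation test can give). A signal that stops growing with depth in narrow regions, as after removal of duplicate fragments, is consistent with a median of 1.35 in 112 narrow non-terminal regions (under 700 bp, as were 12 of the 14 terminal ones) and 1.56 in 307 wide ones (p = 5.0e-05, again the smallest the permutation test can give). The narrow regions still stood well above the terminal ones, so width left most of the difference unaccounted for. Repeat copies with limited signal remain open, and no biological explanation was tested.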
